A study of Mus musculus with 4 samples.

How the data were processed

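Single-cell RNA-seq was made, per the labels, from AT2 cells of Sftpc-creER;Rosa26-mTmG mice, in which tamoxifen labels AT2 cells and their descendants with membrane GFP. GFP-positive, CD45-negative and CD31-negative cells were sorted from lungs of 3 pooled mice per library, at day 0 (PBS) or at day 30 after bleomycin (0.8 U/kg into the trachea), in mice aged 3 or 12 months. The 4 libraries (10x Genomics 3' kit, Illumina sequencing) give 4 groups of 1 library each. The deposited values are counts of unique molecular identifiers per gene and cell barcode. Per the submitters' processing notes they were made with Cell Ranger (version not given in the sources used here) on mouse build mm10, and Seurat 3.2.2 was used. No normalization of the counts was found in the files, which hold whole numbers for 27998 genes.

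Cells with at least 500 genes and at most 20% mitochondrial counts were kept: 2394 of 2452 barcodes (3-month PBS), 2745 of 2807 (12-month PBS), 2624 of 2646 (3-month bleomycin) and 2993 of 3006 (12-month bleomycin). Doublets were scored with Scrublet in scanpy 1.11.5 and kept in the main setting; 48, 63, 56 and 72 barcodes were called at a rate of 0.8% per 1000 barcodes and left out in an alternative. Cells of all libraries were scaled to 10000 counts and log-transformed. They were clustered together on 2000 variable genes, 30 principal components, 15 neighbors and Leiden resolution 0.5 (python-igraph 0.11.9), which gave 12 clusters. A cluster was named from fixed markers of 15 classes found among its 10 genes with the highest ratio to other cells (at 100 CPM and in 20% of its cells), with at least 2 such markers there and at least 3 markers of the class detected. A cluster with fewer than 2 markers of any class there was named AT2-like if at least 3 AT2 markers were detected in it. As 12 AT2 markers were detected in every cluster of the main setting, AT2-like was the default name: each AT2-like cluster of that setting got it in this way, with no AT2 marker among its 10 top genes. The markers were fixed beforehand, but this naming rule was written after the clusters and their top genes had been seen. Clusters named as club, ciliated, basal, macrophage, neutrophil, T or NK, B, endothelial, mesenchymal, mesothelial or erythroid were left out, which left 2354, 2616, 2420 and 2499 alveolar cells with 11077631, 13417020, 21499659 and 31954259 counts. In that depth 1 count equals 0.0903, 0.0745, 0.0465 and 0.0313 CPM.

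Counts were summed over the alveolar cells of each library and scaled to the same library total, as CPM (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15; figures with matplotlib 3.10.9). Log2 ratios use a prior of 0.5 counts; exact conditional-binomial 95% intervals of ratios and Poisson intervals of levels cover counting error only. Differences between the log2 ratios at the 2 ages have intervals from 10000 gamma draws. A gene at 0 counts was set to a floor of 3 counts in its library where a bound is given. With 1 library per group no test was made. Genes at 20 CPM or more in at least 1 of the 2 libraries were counted as higher or lower from 2-fold. For 28 fixed gene lists, members with at least 10 counts over the libraries were used; the median log2 ratio was set against 10000 random lists of the same size, matched in 25 bins of mean expression, and called apart outside their central 95%. Cells were thinned to 3000 counts, the highest multiple of 500 that 80% of cells reach in every library, and to 2000 in an alternative (95% of cells).

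Named genes are the 12 highest and 12 lowest ratios per comparison among counted genes with an interval that leaves out 0, and the 8 highest and 8 lowest differences between the ages, without mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, sex-linked and predicted genes and the markers of other cell types. Up to 4 members per list and comparison are named beside them. The groups, lists, markers and the first set of alternatives were chosen before the data were examined, as were the level, fold and interval limits on genes. Of the list symbols, 5 (Trac, Trbc2, Ighm, Igkc and Ltbp4) are not in the files and were not analysed here. Coordinates are from GENCODE M21 on GRCm38, in which 27722 of 27998 gene identifiers were found (99.0%). Genes that share sequence with ribosomal protein genes, here called ribosomal copies, were found with BLAST 2.17.0 (at least 90% identity to a ribosomal protein transcript over 300 bases). Retrotransposition was not checked, and the genes found include Flt3l and Wdr89.

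The alternatives were median-of-ratios scaling, scaling without the 20 most abundant genes, no filter and a strict filter on cells (1000 genes, 10% mitochondrial counts), called doublets left out, all cells that passed, AT2-like cells alone, every cell weighing the same, thinned cells, minimums of 100 CPM or none beyond 10 counts, Leiden resolution 0.3 and 1 and 15 principal components. Tested on simulated counts, the intervals held the true ratio for 95.9, 95.1, 95.3 and 95.1% of genes in the 4 comparisons, all of 100 genes set to 3-fold were called from 2-fold, and 3.5, 4, 3.5 and 5% of 200 random lists stood apart. These counts were drawn independently per gene from the Poisson model that the intervals assume. The simulation thus checks the computation only, not differences between mice or pools or genes that vary together.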

Results

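The series measured single-cell transcriptomes of alveolar epithelial type 2 (AT2) cells, the surfactant-producing cells of the lung alveolus, from mice aged 3 or 12 months. AT2 cells carried a tamoxifen-induced green fluorescent lineage label driven from the Sftpc promoter, and labelled cells negative for CD45 (leukocytes) and CD31 (endothelium) were sorted. Each of the 4 libraries pooled 3 mice, so every group was 1 library: PBS at day 0 and bleomycin at day 30, at each age. Bleomycin, which injures the alveolar epithelium, was given once into the trachea at 0.8 U/kg. The files held 2452 barcodes and 11381566 counts for 3-month PBS, 2807 and 14214212 for 12-month PBS, 2646 and 23379893 for 3-month bleomycin, and 3006 and 36960380 for 12-month bleomycin. Median counts per cell that passed the filter were 4555, 5080, 8315.5 and 11760 in the same order, so the bleomycin libraries were the deeper ones. With 1 library per group no difference below has a replicate check, and no test was made. Intervals in brackets are exact 95% intervals that cover counting error only. PBS was sampled at day 0 and bleomycin at day 30, so treatment and day of harvest were not separated.

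AT2-like clusters held 2313 of 2394 cells (96.6%, 95.8 to 97.3, Clopper-Pearson) in the 3-month PBS library and 2583 of 2745 (94.1%, 93.2 to 94.95) in the 12-month PBS library. They held 82.7% of 2624 cells (81.2 to 84.2) with bleomycin at 3 months and 2222 of 2993 (74.2%, 72.6 to 75.8) at 12 months. With 15 principal components the bleomycin shares were 69.8% and 42.1%. These shares are given per library and not compared, because AT2-like cells split by library: cluster 8 drew 95.5% of its cells from the 12-month bleomycin library, cluster 1 92.8% from the 12-month PBS library and cluster 2 80.3% from the 3-month bleomycin library. A cluster that mixed AT1 (the flat gas-exchange cell) and transitional alveolar markers held 25, 32, 226 and 163 cells, and was named as a mix of both. A cluster named transitional alveolar-like held 45, 36, 340 and 206 cells with resolution 1 and 65, 59, 568 and 306 with 15 principal components. With resolution 0.3 no such cluster formed, and Cldn4, Hopx, S100a6 and Pmp22 were among the 10 top genes of a club-like cluster. Clusters with ciliated, club, macrophage, mesothelial, or endothelial and mesenchymal markers were left out of the comparisons, which used the remaining 2354, 2616, 2420 and 2499 cells. Sftpc, encoding surfactant protein C (chromosome 14, 70520949 to 70524081, GRCm38), stood between 131132 CPM (counts scaled to the same library total, 3-month PBS) and 158491 (3-month bleomycin).

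In 3-month mice, bleomycin at day 30 against PBS asked how lineage-labelled cells differed after injury. Acute-phase and injury genes were higher: Lcn2, an iron-sequestering innate defence protein (chromosome 2, 32384633 to 32388252, GRCm38), was 7.49-fold higher (7.21 to 7.78), Lrg1 6.86-fold (6.61 to 7.12) and the serum amyloid gene Saa3 30.4-fold (18.03 to 61.6). Of the 18 genes on the injury-activated AT2 and acute phase list, 13 were at least 1.5-fold higher and 1 lower, with a median log2 ratio of 2.09. Keratin and other transitional alveolar genes were higher as well, with a median of 0.91 and 12 of 18 at least 1.5-fold higher. Clu was 4.43-fold higher (4.15 to 4.72), Krt8 1.71-fold (1.63 to 1.80) and Cldn4, a tight junction claudin, 15.4-fold (9.79 to 27.4). In cells thinned to 3000 counts, the transitional alveolar list gave a median of 4 counts per cell with PBS and 5 with bleomycin. The 90th percentiles were 9 and 13 and the 99th 21 and 62.1, so the rise was largest in a few high cells. The cluster that mixed AT1 and transitional alveolar markers, with Cldn4 first among its top genes, was kept in these cells.

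Interferon response genes had a median log2 ratio of 1.39 (16 of 20 at least 1.5-fold higher), MHC class I and antigen processing genes 0.82 (11 of 14) and MHC class II genes 0.69 (6 of 8). Bst2 was 2.59-fold higher (2.27 to 2.98), and Cd74, the class II invariant chain, 1.64-fold (1.62 to 1.65). Macrophage markers summed to 5.42 CPM in the 3-month PBS cells and 32.9 in the 3-month bleomycin cells. The p53 response and senescence list had a median of 0.62, with Phlda3 3.52-fold higher (3.07 to 4.08) and the cell cycle inhibitor Cdkn1a 2.01-fold (1.87 to 2.17). The TGF-beta response and matrix median was 0.54 (mesenchymal markers 2.26), that of NF-kB and TNF response genes 0.58, and that of chemokines and cytokines 1.20. With members at 0 counts in a library set to the floor of 3 counts, the last was 0.51 and the NF-kB median 0.54. Among members at 20 CPM or more the TGF-beta (0.21), NF-kB (0.36) and chemokine (0.14) medians lay within the random range, and the TGF-beta median did in AT2-like cells alone (0.23). Lysosome genes (0.46, Ctsd 2.02-fold, 1.89 to 2.15) and nuclear oxidative phosphorylation genes (0.31, all 25 above 0) were higher, while mitochondrially encoded genes were lower (-0.71, all 13 below 0). Immediate early and dissociation response genes had a median of 0.25 and a mean of -0.18, the 2 differing in sign because the chaperone members Hspa1a and Hspa1b were far lower. Their median lay within the random range in AT2-like cells alone (0.13) and with every cell weighing the same (0.23).

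Cholesterol synthesis genes were lower, with a median of -0.44 and 6 of 18 at least 1.5-fold lower. Cytosolic ribosomal protein genes had a median of -0.39. Medians of the surfactant and AT2 identity list (0.04), AT1 genes (0.23), proliferation (-0.11), YAP targets (0.24), Wnt targets (-0.30), Notch genes (0.55), FGF response (-0.05), unfolded protein response (0.03), fatty acid and phospholipid synthesis (0.02), glycolysis (0.29), antioxidant NRF2 targets (0.27) and cell junctions (0.14) lay within the central 95% of random lists. AT1 genes had a median of -0.42 in AT2-like cells alone, below that range, but 0.62 with every cell weighing the same, 0.45 in thinned cells and 0.35 in cells without a macrophage-marker count, above it. Under the same 3 settings the proliferation median was -0.48, -0.46 and -0.69, below the range. The YAP target median was 0.48 with every cell weighing the same, above the range, and -0.68 among members at 20 CPM or more. Glycolysis genes stood above the range in all cells that passed the filter (0.41), with every cell weighing the same (0.36), in thinned cells (0.32), in cells without a macrophage-marker count (0.32) and among members at 20 CPM or more (0.48). NRF2 targets did so in thinned cells (0.35). Wnt targets lay below it in AT2-like cells alone (-0.37) and under the strict filter on cells (-0.31), and the FGF response among members at 20 CPM or more (-0.44). The Notch median was 0 with members at the floor.

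Among single genes, Kng2 was 25.9-fold higher (16.4 to 47.0), Itm2a 14.1-fold (11.4 to 17.8), the clock output factor Dbp 24.0-fold (18.3 to 32.8), Ly6i 8.62-fold (6.27 to 12.5), Fgg 6.99-fold (5.16 to 9.91), Slc26a4 6.97-fold (5.44 to 9.22) and Col6a2 6.47-fold (4.93 to 8.80). The non-coding RNA Meg3 had 1 count in the PBS cells and a ratio of 280 (75.2 to 16627). With 0 counts in PBS, the secreted matrix protein gene Spp1 was at least 55.8-fold higher, while also among the 10 top genes of the left-out macrophage-like cluster, and Cfb, encoding complement factor B, at least 14.8-fold. The inducible chaperone genes Hspa1b and Hspa1a were 44.2-fold (36.4 to 54.8) and 17.6-fold (15.3 to 20.4) lower, and Hsph1 8.56-fold (7.10 to 10.4). Hspa1a and Hspa1b are near-identical neighbours on chromosome 17, so how counts divide between them is uncertain. Bex1 was 10.7-fold lower (8.24 to 14.1), Batf 7.44-fold (5.64 to 10.1), the lipoprotein lipase gene Lpl 7.42-fold (5.82 to 9.64), Ppp1r1a 6.06-fold (4.83 to 7.70), Mgll 5.86-fold (4.75 to 7.30), Bex4 5.14-fold (4.88 to 5.41) and Pon1 5.04-fold (4.17 to 6.15). The pseudogenes Rps26-ps1 and Rpl36-ps3, which share sequence with ribosomal protein genes, were 7.34-fold (6.72 to 8.03) and 6.97-fold (6.18 to 7.90) lower. Across 4844 genes at 20 CPM or more, 141 were at least 2-fold higher and 156 at least 2-fold lower. These were 126 and 170 with median-of-ratios scaling, 165 and 137 with scaling without the 20 most abundant genes, and 141 and 131 without pseudogenes and ribosomal copies.

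**Figure D1:**
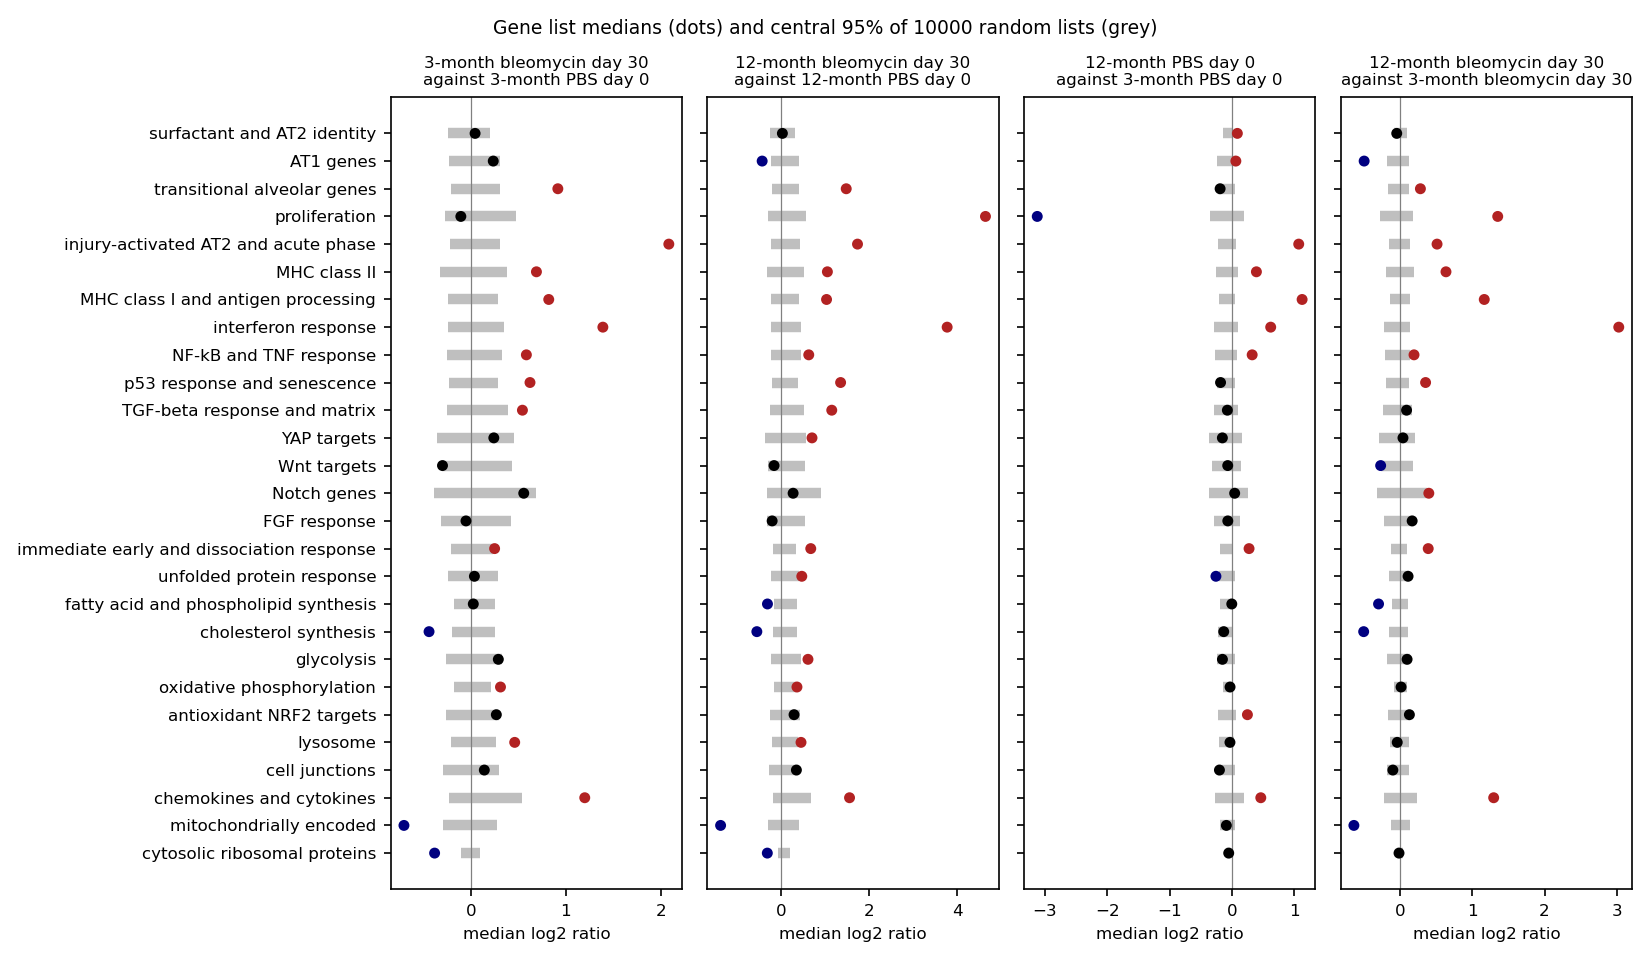
Median log2 ratio (horizontal axis) of each gene list (vertical axis) in the 4 comparisons; dots are medians of summed CPM (red above, blue below, black within the range), and grey bars the central 95% of 10000 random lists of matched expression. The interferon response median was 1.39 in 3-month and 3.78 in 12-month mice for bleomycin against PBS, and 3.03 for the 2 bleomycin libraries against each other.

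In 12-month mice, the same comparison showed interferon response genes as the list with the second-highest median after proliferation: 3.78, with all 20 members at least 1.5-fold higher. Ifitm3, an antiviral membrane protein gene, was 32.6-fold higher (28.3 to 37.9), Isg15 31.2-fold (25.3 to 39.3), Ifi27l2a 12.2-fold (11.5 to 13.1) and Iigp1 108-fold (56.2 to 289). Ifit1 had 2 counts in PBS and a ratio of 108 (37.3 to 1119). MHC class I and antigen processing genes had a median of 1.03 with all 14 at least 1.5-fold higher, and B2m, the class I light chain, was 2.18-fold higher (2.16 to 2.21). For MHC class II the median was 1.05; H2-Eb1 (chromosome 17, 34305867 to 34316674, GRCm38) was 17.3-fold higher (15.7 to 19.2) against 2.09-fold (2.07 to 2.10) for Cd74. The left-out macrophage-like cluster may also hold T or NK cells, which formed no separate cluster in the main setting. In its cells, H2-Eb1 stood at 58.7 CPM (12 counts) with PBS and 1459 with bleomycin. There H2-Aa stood at 5696 and 5144, H2-Ab1 at 3812 and 4083, and Cd74 at 12483 and 11850 CPM. The H2-Eb1 difference was thus not particular to the alveolar cells. Macrophage markers summed to 17.1 CPM in the 12-month PBS cells and 112 in the 12-month bleomycin cells.

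Transitional alveolar genes had a median of 1.48, 16 of 18 being at least 1.5-fold higher, among them Cldn4 (26.6-fold, 15.4 to 55.9), Clu (5.91-fold, 5.59 to 6.26), Krt18 (2.67-fold, 2.57 to 2.79) and Krt8 (2.61-fold, 2.495 to 2.74). In cells thinned to 3000 counts, the transitional alveolar list gave medians of 3 and 7 counts per cell with PBS and bleomycin. The 99th percentiles were 17 and 73. The p53 response and senescence median was 1.35, with Phlda3 5.08-fold higher (4.50 to 5.78) and Cdkn1a 4.83-fold (4.48 to 5.22). TGF-beta response and matrix genes stood at 1.15, beside mesenchymal markers at 3.61 (3.95 and 25.004 CPM in sum), YAP targets at 0.70, NF-kB and TNF response genes at 0.63, and immediate early and dissociation genes at 0.67. The YAP target median was -0.27 among members at 20 CPM or more. It lay within the random range in thinned cells (0.60) and in all cells that passed the filter (0.55). Injury-activated AT2 and acute phase genes had a median of 1.74, or 1.10 with members at 0 counts set to the floor; Lcn2 was 5.09-fold (4.99 to 5.18) and Saa3 10.5-fold (7.86 to 14.6) higher. Chemokines and cytokines had a median of 1.56, or 0.99 with such members at the floor, and Cxcl2 was 20.9-fold higher (17.2 to 26.1). The chemokine (0.69) and NF-kB (0.62) medians lay within the random range among members at 20 CPM or more. Proliferation genes had a median of 4.65 (4.33 with members at the floor), all 15 being higher, from 19.8 to 188 CPM in sum. Ube2c and Hist1h2ap had 2 and 5 counts in PBS, with ratios of 124 (42.6 to 1277) and 76.5 (35.9 to 259).

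Glycolysis genes were higher (median 0.61), Eno1 4.99-fold (4.45 to 5.62) and Gapdh 3.33-fold (3.23 to 3.44), although Hk2 was 3.38-fold lower (3.13 to 3.65). Medians were also higher for the unfolded protein response (0.47), lysosome (0.45) and oxidative phosphorylation (0.36); that of lysosome genes lay within the random range among members at 20 CPM or more (0.45). Lipid genes were lower: cholesterol synthesis had a median of -0.55 with 8 of 18 at least 1.5-fold lower, and fatty acid and phospholipid synthesis -0.31. Scd1, a fatty acid desaturase gene, was 2.12-fold lower (2.10 to 2.14). Mitochondrially encoded genes (-1.38, all 13 at least 1.5-fold lower) and cytosolic ribosomal protein genes (-0.32) were lower. The AT1 median was -0.43 but 0.13 with cells thinned to a fixed depth. Summed AT1 genes were higher, at 2874 CPM with PBS and 3774 with bleomycin. In cells thinned to 3000 counts they gave medians of 7 and 10 counts per cell. Surfactant and AT2 identity (0.03), Wnt targets (-0.16), Notch genes (0.27), FGF response (-0.21), antioxidant NRF2 targets (0.29) and cell junctions (0.35) lay within the central 95% of random lists. Among members at 20 CPM or more the Wnt target median was 1.003, the Notch median -1.19 and the FGF response median -0.40, all outside that range, as were the Wnt target medians in thinned cells (-0.32) and in cells without a macrophage-marker count (-0.33).

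Other genes with the highest ratios were Jchain and Spp1, each with 2 counts in PBS, at 460 (159 to 4747) and 167 (57.6 to 1726), Meg3 (71.2-fold, 44.5 to 132) and Kng2 (20.3-fold, 14.8 to 29.5). Spp1 is among the 10 top genes of the macrophage-like cluster and Jchain of the mixed endothelial and mesenchymal cluster, both left out of these cells. With 15 principal components Jchain ranked first, before Mzb1 and Cd79a, in a separate B-like cluster. The lowest were Igfbp2 (45.1-fold lower, 27.7 to 84.2), Lpl (15.5-fold, 12.5 to 19.6), Bex2 (12.2-fold, 11.5 to 12.9), Pon1 (12.0-fold, 10.2 to 14.4), Cst8 (9.62-fold, 8.76 to 10.6), Mgll (8.99-fold, 7.24 to 11.3) and Cyp2b10 (8.30-fold, 7.44 to 9.30). Igfbp6 (8.24-fold, 7.53 to 9.03), Prmt8 (7.82-fold, 6.82 to 9.02), Ppp1r1b (7.22-fold, 6.01 to 8.77), the pseudogene Rps18-ps3 (6.53-fold, 6.25 to 6.83) and Bex4 (6.44-fold, 6.15 to 6.75) followed. Of 4736 genes, 339 were at least 2-fold higher and 195 lower; with median-of-ratios scaling these were 268 and 237.

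Between the PBS libraries, which compare 12 with 3 months without injury, antigen presentation and injury genes were higher at 12 months and heat-shock genes lower. MHC class I and antigen processing genes had a median log2 ratio of 1.12, all 14 above 0: H2-Q7 was 8.92-fold higher (7.15 to 11.4), B2m 3.17-fold (3.10 to 3.25), Psmb8, an immunoproteasome subunit gene, 2.51-fold (2.32 to 2.71), and H2-D1 2.21-fold (2.17 to 2.26). H2-Q7 and H2-Q6 (3.83-fold, 3.12 to 4.78) are close paralogs, so their separate values are uncertain. From 3 to 12 months, macrophage markers stood at 5.42 and 17.1, T or NK markers at 0.0903 and 3.65, and club markers at 3403 and 7140 CPM in the same cells. Injury-activated AT2 and acute phase genes had a median of 1.07, with Retnla, also among the 10 top genes of the left-out club-like cluster, 24.7-fold (20.7 to 29.9) and Lcn2 3.67-fold (3.52 to 3.82) higher. Medians were also above random lists for interferon response (0.62), chemokines and cytokines (0.46), MHC class II (0.39), NF-kB and TNF response (0.32), immediate early and dissociation response (0.27, mean -0.39), antioxidant NRF2 targets (0.25), surfactant and AT2 identity (0.08) and AT1 genes (0.06). The NF-kB median was 0.29 with members at the floor. The NF-kB and chemokine medians were -0.04 and -0.05 among members at 20 CPM or more, and that of AT1 genes was -0.23 in AT2-like cells alone.

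Proliferation genes had a median of -3.12 (-2.96 with members at the floor), from 90.2 to 19.8 CPM in sum; the proliferating-like cluster held 16 cells of the 3-month and 1 cell of the 12-month PBS library. That cluster held 23 and 114 cells of the 3-month and 12-month bleomycin libraries. The unfolded protein response median was -0.26. Hspa1b was 58.4-fold lower at 12 months (44.2 to 80.5), Hspa1a 44.9-fold (34.4 to 60.9), Hsph1 11.6-fold (8.96 to 15.5), Hspb1 3.64-fold (3.40 to 3.90), Serpinh1 3.08-fold (2.81 to 3.38), Stip1 3.03-fold (2.65 to 3.49), Ahsa2 2.87-fold (2.31 to 3.59), Dnajb1 2.83-fold (2.55 to 3.15) and Hspa4l 2.56-fold (2.14 to 3.09). Hist1h2ap (56.9-fold, 26.4 to 194), S100a6 (2.99-fold, 2.81 to 3.18) and Rgs10 (2.82-fold, 2.43 to 3.27) were lower too. Higher genes included Ly6i (22.0-fold, 16.1 to 31.8), Pigr (12.9-fold, 8.77 to 20.6), Dbp (10.6-fold, 8.04 to 14.6), Cxcl1 (5.47-fold, 4.25 to 7.21), Slc6a20a (4.71-fold, 3.73 to 6.07), Ly6a (4.68-fold, 3.71 to 6.02), Igfbp2 (4.37-fold, 3.29 to 5.98), Prmt8 (4.23-fold, 3.59 to 5.02) and Slc26a4 (3.78-fold, 2.89 to 5.07). Haemoglobin and other erythroid markers had 146 counts in the 3-month PBS cells and 0, 8 and 4 counts in the other 3 libraries.

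Medians for transitional alveolar (-0.19), p53 (-0.18), TGF-beta (-0.08), YAP (-0.16), Wnt (-0.07), Notch (0.04), FGF (-0.07), fatty acid (0.00), cholesterol (-0.13), glycolysis (-0.15), oxidative phosphorylation (-0.03), lysosome (-0.03), cell junction (-0.20), mitochondrially encoded (-0.09) and ribosomal protein (-0.05) genes lay within the random range. Outside it were transitional alveolar (-0.31), TGF-beta (-0.64) and Wnt (-0.45) medians among members at 20 CPM or more, transitional alveolar (-0.25) and TGF-beta (0.15) medians with every cell weighing the same, and the YAP median in AT2-like cells alone (-0.53). The median of all genes was -0.11 in this comparison and -0.01 with median-of-ratios scaling, a shift of 0.10 against which these values are to be read. Of 4547 genes, 43 were at least 2-fold higher and 35 lower; with median-of-ratios scaling these were 49 and 26.

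**Figure D2:**
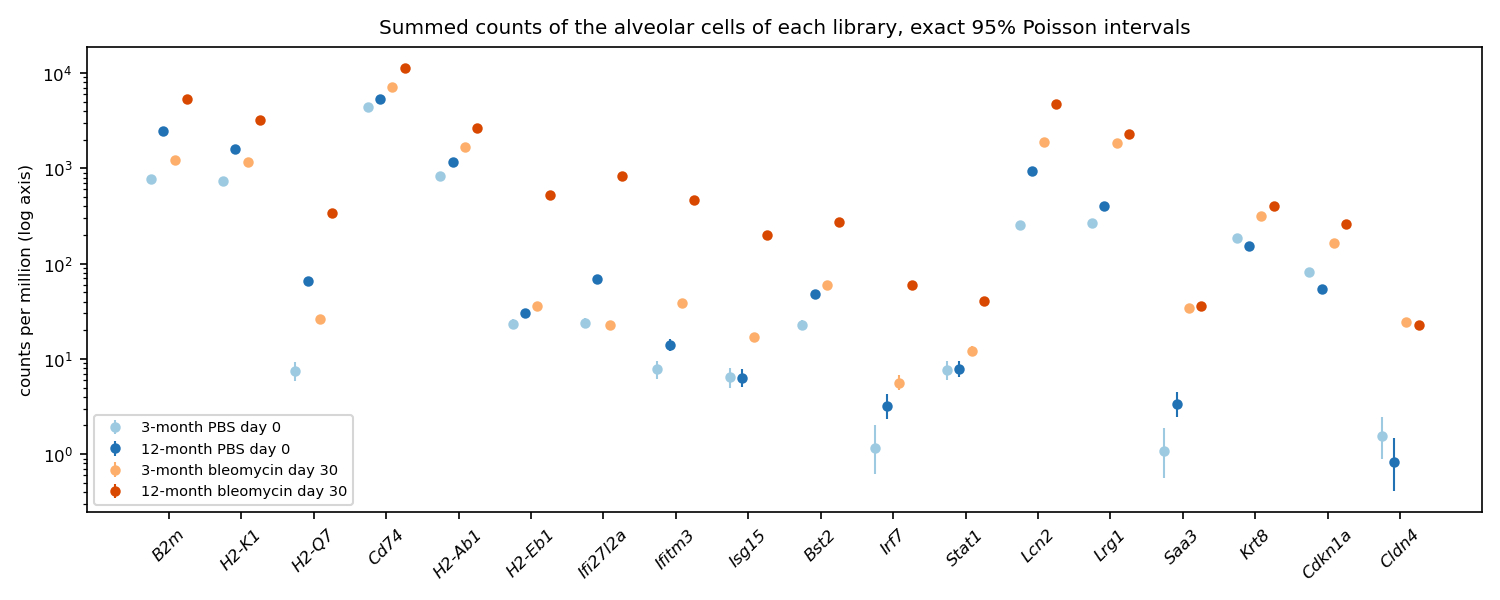
CPM (vertical, log axis) of 18 genes in the summed alveolar cells of the 4 libraries, with exact 95% Poisson intervals that cover counting error only. H2-Eb1 stood at 23.4, 29.96, 36.1 and 520 CPM in 3-month PBS, 12-month PBS, 3-month bleomycin and 12-month bleomycin.

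Between the bleomycin libraries, interferon and antigen presentation genes were higher at 12 than at 3 months. The interferon response median was 3.03 with all 20 members at least 1.5-fold higher: Iigp1 was 66.7-fold higher (43.7 to 114), Ifi27l2a 36.9-fold (33.7 to 40.5), Ifit1 15.2-fold (10.6 to 23.5), Ifitm3 12.0-fold (11.2 to 12.9), Isg15 11.6-fold (10.5 to 12.97) and Irf7, an interferon regulatory factor gene, 10.5-fold (8.77 to 12.8). For MHC class I and antigen processing the median was 1.17, with H2-Q7 12.96-fold (11.9 to 14.1) and B2m 4.40-fold (4.34 to 4.46) higher. The MHC class II median was 0.64: H2-Eb1 was 14.4-fold higher (13.4 to 15.5), while H2-Aa was 1.34-fold (1.33 to 1.36) and Cd74 1.57-fold (1.56 to 1.58) higher. In cells thinned to 3000 counts, the interferon list gave a median of 4 counts per cell in the 12-month bleomycin library and 0 in each of the other 3, with a 10th percentile of 1 in the former. In cells thinned to 2000 counts these values were 3, 0 and 0. Macrophage markers summed to 32.9 and 112 CPM in the 3-month and 12-month bleomycin cells. In cells of the left-out macrophage-like cluster, which may hold T or NK cells as well, H2-Eb1 stood at 66.5 CPM in the 3-month and 1459 in the 12-month bleomycin library. There H2-Aa stood at 5993 and 5144, H2-Ab1 at 3884.5 and 4083, and Cd74 at 12760 and 11850 CPM. The H2-Eb1 difference was thus not particular to the alveolar cells.

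Proliferation genes had a median of 1.35 and chemokines and cytokines 1.30 (Cxcl2 15.9-fold, 13.8 to 18.5). Injury-activated AT2 and acute phase genes stood at 0.51 (Lcn2 2.49-fold, 2.47 to 2.52). Medians were 0.40 for Notch genes, 0.39 for immediate early and dissociation genes and 0.36 for p53 response and senescence genes. They were 0.28 for transitional alveolar genes and 0.19 for NF-kB and TNF response genes. Ccl5, which is not on the chemokine list, was 12.5-fold higher (9.44 to 17.1). It led the top genes of a T or NK-like cluster with 15 principal components. With cells thinned to a fixed depth the Notch median was -0.08 and the Wnt target median -0.03, and the chemokine median was 0.24 among members at 20 CPM or more. Notch genes stood at -0.37 in all cells that passed the filter and at 0.24, within the random range, in cells without a macrophage-marker count. Wnt targets lay within that range under the strict filter (-0.25) and with every cell weighing the same (-0.24). They also did so among members at 20 CPM or more (-0.065), in all cells that passed (-0.13) and in cells without such a count (-0.13). Lower medians belonged to cholesterol synthesis (-0.50, all 18 below 0), AT1 genes (-0.49), fatty acid and phospholipid synthesis (-0.30), Wnt targets (-0.27) and mitochondrially encoded genes (-0.64). Scd1 was 1.95-fold lower at 12 months (1.94 to 1.97) and Srebf1, a lipogenic transcription factor gene, 1.75-fold (1.63 to 1.87). The AT1 gene Rtkn2 was 3.01-fold (2.37 to 3.85) and Vegfa 1.74-fold (1.61 to 1.88) lower.

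Ly6i (11.3-fold, 10.5 to 12.3) and the GTPase gene Igtp (9.84-fold, 8.19 to 12.0) were among the highest. Lowest were Cox6a2 (3.57-fold lower, 3.37 to 3.78), Dbp (3.29-fold, 3.06 to 3.54), Cbr2 (2.87-fold, 2.83 to 2.91), Id3 (2.84-fold, 2.496 to 3.25), Cst8 (2.79-fold, 2.51 to 3.10), Lpar3 (2.78-fold, 2.36 to 3.28), Rasd2 (2.57-fold, 2.20 to 3.01) and Mfsd2a (2.49-fold, 2.28 to 2.72). Ano1 (2.33-fold, 2.03 to 2.68), Rsrp1 (2.30-fold, 2.20 to 2.41), Sema3b (2.26-fold, 1.956 to 2.61) and Apoe (2.21-fold, 2.17 to 2.26) followed. Surfactant and AT2 identity (-0.04), TGF-beta (0.09), YAP (0.04), FGF (0.17), unfolded protein response (0.11), glycolysis (0.10), oxidative phosphorylation (0.02), NRF2 (0.13), lysosome (-0.04), cell junction (-0.10) and ribosomal protein (-0.01) medians lay within the random range. In AT2-like cells alone the TGF-beta (0.55) and YAP (0.49) medians stood above it, as did the TGF-beta (0.31) and glycolysis (0.16) medians in all cells that passed the filter and the unfolded protein response median in thinned cells (0.15) and in cells without a macrophage-marker count (0.14). The surfactant and AT2 identity median was below it in all cells that passed (-0.11). Of 4641 genes, 94 were at least 2-fold higher and 23 lower, the latter 14 in cells without a macrophage-marker count; without the 20 most abundant genes in the scaling these were 89 and 30.

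Markers of other cell types were measured in the same alveolar cells, after clusters of these types were left out. In the order 3-month PBS, 12-month PBS, 3-month bleomycin and 12-month bleomycin, summed CPM were 3403, 7140, 4912 and 4281 for club, 358, 254, 251 and 124 for ciliated, and 0.361, 0.298, 7.77 and 1.53 for basal markers. Macrophage markers stood at 5.42, 17.1, 32.9 and 112, neutrophil markers at 13.2, 14.6, 8.70 and 101, T or NK markers at 0.0903, 3.65, 2.42 and 15.3, and B markers at 92.1, 81.8, 178 and 152. Endothelial markers gave 19.0, 23.3, 52.7 and 37.2, mesenchymal markers 3.34, 3.95, 11.9 and 25.004, and mesothelial markers 0.271, 1.86, 14.4 and 11.8. Sex-linked genes summed to 75.7, 74.5, 82.6 and 87.5, with median log2 ratios of 0.17, 0.02, 0.02 and -0.03 in the 4 comparisons. Macrophage, neutrophil and T or NK sums were each highest in the 12-month bleomycin library, where interferon and MHC genes were highest as well. Ccl5 ranked first in a T or NK-like cluster that 15 principal components separated.

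Ratios of bleomycin to PBS at the 2 ages had a Pearson r of 0.745 and a Spearman rho of 0.763 across 5071 genes, which are not independent replicates, and 79.2% of genes lay on the same side of 0. The interferon response median against PBS was 1.39 at 3 and 3.78 at 12 months, a difference that was not tested. Among the genes with the highest differences, the difference of log2 ratios (12-month minus 3-month) was 4.20 for Ifit1 (1.35 to 7.16), 3.70 for Ifi27l2a (3.47 to 3.93) and 3.56 for Isg15 (3.07 to 4.02). Cell cycle genes Ube2c (9.25, 7.86 to 11.90) and Hist1h2ap (7.01, 5.99 to 8.55) and the chaperone genes Hspa1a (5.75, 5.32 to 6.24), Hspa1b (5.32, 4.77 to 5.91) and Hsph1 (3.59, 3.12 to 4.11) also had the highest differences; each of these 5 stood higher in the 3-month than in the 12-month PBS library. At the other end were Igfbp2 (-5.34, -6.31 to -4.51), Dbp (-5.13, -5.58 to -4.73), Prmt8 (-3.02, -3.36 to -2.70), Tex11 (-2.82, -3.25 to -2.41), Cyp4b1 (-2.76, -3.20 to -2.34), Tef (-2.50, -2.90 to -2.13), Pigr (-2.37, -3.03 to -1.78) and Pmp22 (-2.29, -2.69 to -1.90). In all, 123 genes differed by at least 2-fold towards higher and 79 towards lower ratios at 12 months. These counts depend on the scaling and the cells: 109 and 86 with median-of-ratios scaling, 101 and 93 with scaling without the 20 most abundant genes, and 120 and 114 in all cells that passed the filter.

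**Figure D3:**
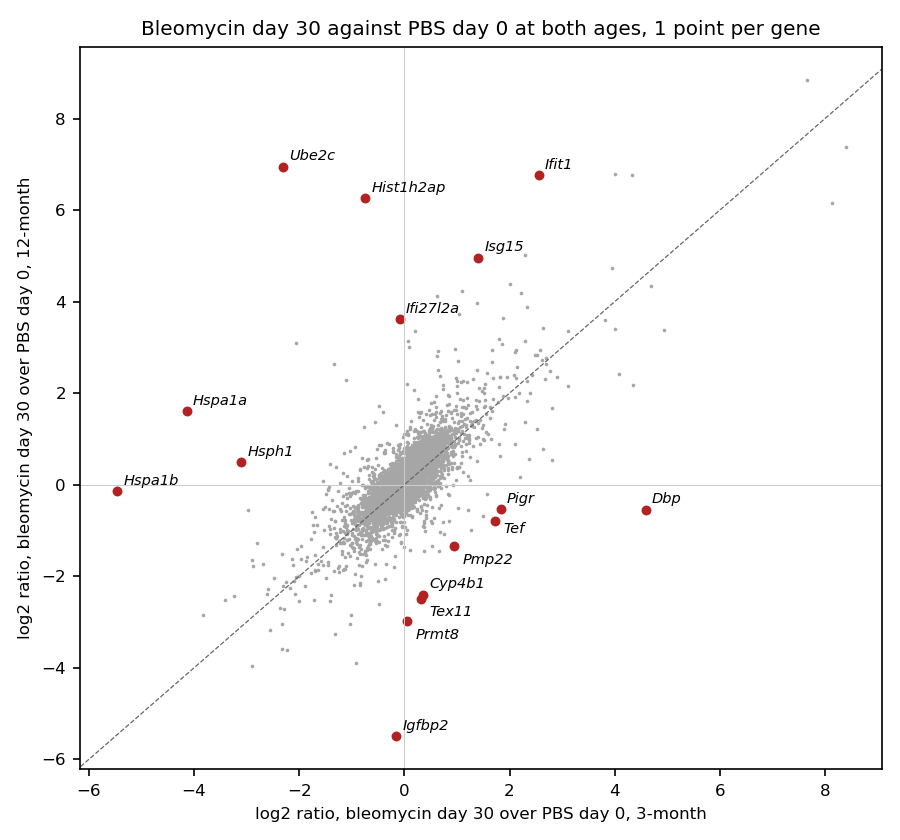
Log2 ratio of bleomycin day 30 over PBS day 0 in 3-month (horizontal) against 12-month mice (vertical), 1 grey point per gene at 20 CPM or more in any library; red points are the 8 highest and 8 lowest differences among ranked genes and the dashed line marks equal ratios. Ube2c lay at -2.30 and 6.95, and Dbp at 4.59 and -0.54.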

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

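The tests of time of day and of a general dissociation response were chosen only after the result was seen. The difference between the ages in the ratio of bleomycin to PBS was not tested for any gene, since each group was 1 library.

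Genes whose ratio of bleomycin to PBS lay in opposite directions at the 2 ages drew attention by that difference. Ube2c (9.25 on the log2 scale, 12-month minus 3-month), Hist1h2ap (7.01), Hspa1a (5.75) and Hsph1 (3.59) were lower with bleomycin at 3 months and higher at 12. Dbp (-5.13), Tex11 (-2.82), Cyp4b1 (-2.76), Tef (-2.50), Pigr (-2.37) and Pmp22 (-2.29) were higher at 3 months and lower at 12.

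Heat-shock genes in this set were highest in the 3-month PBS library, while clock genes differed in both 3-month libraries, in opposite directions: Dbp stood at 4.51, 48.4, 109.5 and 33.3 CPM and Arntl at 17.6, 7.98, 2.79 and 6.82 (3-month PBS, 12-month PBS, 3-month bleomycin, 12-month bleomycin). A general dissociation response, one that also raises immediate early genes, is argued against by those other than chaperones. They were lower in the 3-month than in the 12-month PBS library (median 0.46, 12 over 3 months). That set leaves out the chaperones, so it cannot decide on a dissociation response limited to heat-shock genes, which stays open. A different time of day at harvest may have contributed: the clock genes Arntl, Npas2, Cry1, Clock and Nfil3 had a median lower than that of Dbp, Tef, Nr1d1, Nr1d2, Per2, Per3 and Ciart in 12-month against 3-month PBS (difference -2.50), and the medians were 0.69 and -0.91 between the bleomycin libraries. Dbp and Tef had been seen before the second set was written. This and the age of the mice, which was not tested, stay open.

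Clusters of other cell types, left out of the comparisons, drew attention where the exact 95% interval of their share lay above that of the PBS library of the same age. These intervals cover the sampling of cells only and, with 1 library per group, do not show a difference between groups. In the 3-month bleomycin library they were ciliated-like (1.83% of cells), endothelial and mesenchymal (1.71%), club-like (1.22%), macrophage-like (2.44%) and mesothelial-like (0.572%). In the 12-month bleomycin library they were club-like (2.07%), macrophage-like (10.4%) and mesothelial-like (0.601%), after a sort meant to leave out CD45-positive and CD31-positive cells. Shares of ciliated-like (1.06% with PBS, 1.504% with bleomycin) and endothelial and mesenchymal cells (1.09% and 1.90%) were also higher at 12 months, with intervals that overlapped. The latter cluster is mixed: with resolution 1 the share at 12 months was 0.911% with PBS and 0.468% with bleomycin for endothelial-like and 0.219% and 1.44% for mesenchymal-like cells. Jchain and Mzb1 came first among the 10 top genes of that mesenchymal-like cluster, so it was itself mixed. With 15 principal components a mesenchymal-like cluster held 5 cells of the 12-month PBS and 20 of the 12-month bleomycin library. A separate B-like cluster then held 7 and 42 cells (0.255% and 1.40%). At 3 months, resolution 1 gave 12 endothelial-like cells with PBS and 33 with bleomycin, and 4 and 12 mesenchymal-like cells. The intervals of both shares overlapped between the libraries. With resolution 1 the macrophage-like share in 12-month bleomycin was 6.88%, beside a T or NK-like share of 3.58% that was no separate cluster in the main setting (1.60% and 0.838% in 3-month bleomycin). Club-like clusters depended on the setting. They held 32 and 62 cells of the 3-month and 12-month bleomycin libraries, 156 and 141 with resolution 0.3, and 28 and 877 with 15 principal components.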

How the results depend on the processing

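The alternatives in cells without a macrophage-marker count and without pseudogenes and ribosomal copies were chosen after seeing the data. Of 1660 list medians recomputed under alternatives, 1560 kept their place inside or outside the random range and, where the main value lay outside, their sign; the sign of medians inside it was not compared. Of the others, 15 outside it changed sign, 36 no longer stood apart, 39 came to stand apart on the side of their main sign and 10 on the opposite side. Of 108 main medians of lists other than cell-type markers and sex-linked genes, 73 were kept under every alternative run, 48 of them among the 64 that stood apart. Of 13250 recomputed gene ratios, 10967 stayed within the counting interval, 2278 lay outside it and 5 reversed. A reversal was counted only where the main ratio was at least 1.5-fold with an interval that left out 0. The sign of other gene ratios was not compared. With a minimum of 100 CPM, genes at least 2-fold higher and lower numbered 37 and 62 (3-month bleomycin against PBS), 99 and 60 (12-month bleomycin against PBS), 14 and 12 (the PBS libraries) and 36 and 8 (the bleomycin libraries). Without a minimum beyond 10 counts, genes at least 2-fold higher and lower numbered 1205 and 635 (3-month bleomycin against PBS), 1971 and 857 (12-month bleomycin against PBS), 436 and 455 (the PBS libraries) and 924 and 435 (the bleomycin libraries). More or fewer genes are counted by construction. Cells without a macrophage-marker count gave 14 genes lower between the bleomycin libraries. List medians for which this place, or the sign of one outside the range, differed follow, with the main value in brackets, for lists other than cell-type markers; marker lists are given only where the sign of one outside the range changed. In AT2-like cells alone, these were, for 3-month bleomycin against PBS, AT1 genes -0.42 (0.23), TGF-beta response and matrix 0.23 (0.54), Wnt targets -0.37 (-0.30) and immediate early and dissociation response 0.13 (0.25). Values for the PBS libraries were AT1 genes -0.23 (0.061) and YAP targets -0.53 (-0.16). Values for the bleomycin libraries were TGF-beta response and matrix 0.55 (0.092) and YAP targets 0.49 (0.042). With every cell weighing the same, these were, for 3-month bleomycin against PBS, AT1 genes 0.62 (0.23), proliferation -0.48 (-0.11), YAP targets 0.48 (0.24), immediate early and dissociation response 0.23 (0.25) and glycolysis 0.36 (0.29). For the PBS libraries: transitional alveolar genes -0.25 (-0.19) and TGF-beta response and matrix 0.15 (-0.075). For the bleomycin libraries: Wnt targets -0.24 (-0.27). With cells thinned to a fixed depth, these were, for 3-month bleomycin against PBS, AT1 genes 0.45 (0.23), proliferation -0.46 (-0.11), glycolysis 0.32 (0.29) and antioxidant NRF2 targets 0.35 (0.27). Values for 12-month bleomycin against PBS were AT1 genes 0.13 (-0.43), YAP targets 0.60 (0.70) and Wnt targets -0.32 (-0.16). Values for the PBS libraries were AT1 genes -0.027 (0.061). Values for the bleomycin libraries were Wnt targets -0.033 (-0.27), Notch genes -0.076 (0.40) and unfolded protein response 0.15 (0.11). In cells without a macrophage-marker count, these were, for 3-month bleomycin against PBS, AT1 genes 0.35 (0.23), proliferation -0.69 (-0.11) and glycolysis 0.32 (0.29). For 12-month bleomycin against PBS: AT1 genes 0.055 (-0.43), Wnt targets -0.33 (-0.16) and erythroid markers 0.73 (-1.25). In the main setting erythroid markers had 0 counts with PBS and 4 with bleomycin at 12 months. Their main value thus reflects the prior of 0.5 counts and the library totals, not a measured level. For the PBS libraries: AT1 genes -0.023 (0.061). For the bleomycin libraries: Wnt targets -0.13 (-0.27), Notch genes 0.24 (0.40), unfolded protein response 0.14 (0.11) and erythroid markers 1.08 (-1.36). The last rests on 8 counts in the 3-month and 4 in the 12-month bleomycin cells of the main setting. Among members at 20 CPM or more, these were, for 3-month bleomycin against PBS, NF-kB and TNF response 0.36 (0.58), TGF-beta response and matrix 0.21 (0.54), YAP targets -0.68 (0.24), FGF response -0.44 (-0.055), glycolysis 0.48 (0.29), chemokines and cytokines 0.14 (1.20) and ciliated markers -0.62 (0.92). Values for 12-month bleomycin against PBS were AT1 genes -0.13 (-0.43), NF-kB and TNF response 0.62 (0.63), YAP targets -0.27 (0.70), Wnt targets 1.003 (-0.16), Notch genes -1.19 (0.27), FGF response -0.40 (-0.21), lysosome 0.45 (0.45) and chemokines and cytokines 0.69 (1.56). Values for the PBS libraries were AT1 genes -0.12 (0.061), transitional alveolar genes -0.31 (-0.19), NF-kB and TNF response -0.039 (0.32), TGF-beta response and matrix -0.64 (-0.075), Wnt targets -0.45 (-0.07), chemokines and cytokines -0.048 (0.46) and ciliated markers -0.39 (0.73). Values for the bleomycin libraries were proliferation 1.42 (1.35), Wnt targets -0.065 (-0.27) and chemokines and cytokines 0.24 (1.30). Under the strict filter on cells, these were, for 3-month bleomycin against PBS, Wnt targets -0.31 (-0.30). For the PBS libraries: AT1 genes 0.038 (0.061). For the bleomycin libraries: Wnt targets -0.25 (-0.27). With all cells that passed the filter, these were, for 3-month bleomycin against PBS, glycolysis 0.41 (0.29). Values for 12-month bleomycin against PBS were YAP targets 0.55 (0.70). Values for the bleomycin libraries were surfactant and AT2 identity -0.11 (-0.044), TGF-beta response and matrix 0.31 (0.092), Wnt targets -0.13 (-0.27), Notch genes -0.37 (0.40) and glycolysis 0.16 (0.099). The AT2-like share of cells was, in percent, 95.5 in 3-month PBS with resolution 1 (96.6), 77.9 in 3-month bleomycin with resolution 1 (82.7), 94.6 in 3-month PBS with 15 principal components (96.6), 69.8 in 3-month bleomycin with 15 principal components (82.7), 42.1 in 12-month bleomycin with 15 principal components (74.2) and 94.6 in 3-month PBS with the strict filter (96.6). It was also 72.4 in 3-month bleomycin with the strict filter (82.7), 76.4 in 12-month bleomycin with the strict filter (74.2), 95.1 in 3-month PBS with called doublets left out (96.6), 76.9 in 12-month bleomycin with called doublets left out (74.2), 86.7 in 3-month bleomycin with resolution 0.3 (82.7) and 77.8 in 12-month bleomycin with resolution 0.3 (74.2). Single genes counted as reversed by this rule were Dynlrb2 (0.12 against -0.92, 3-month bleomycin against PBS, all cells that passed), Scgb3a2 (0.60 against -1.04, the PBS libraries, all cells that passed), Cyp2f2 (-0.16 against 0.98, the bleomycin libraries, all cells that passed), Timp3 (-0.35 against 0.63, 3-month bleomycin against PBS, AT2-like cells alone) and S100a6 (-0.23 against 1.10, 12-month bleomycin against PBS, AT2-like cells alone). With 15 principal components 877 cells of 12-month bleomycin lay in a cluster named club-like (62 in the main setting), with Ly6i, Iigp1 and Isg15 among its 10 top genes; whether these cells were AT2-like in the main setting was not counted. With called doublets left out, a cluster of 20 cells with Jchain and Mzb1 at its top was named AT2-like, as was one of 25 cells with Ccl5 at its top under the strict filter. Apart from these and the minimum on counts, the cause was not tested. A member at 0 counts was held by 23 of 108 medians, which differ by at most 0.69 with such members at the floor. Leaving out a library was not possible with 1 per group. No paired analysis was possible because each group had 1 library of pooled mice.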

Other observations

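Among the tests below, those of depth per cell, of cells without a macrophage-marker count and of ribosomal transcript content were chosen only after the result was seen (thinning of cells had itself been chosen beforehand), as were the alternative limits of 200 aligned bases and of 20 CPM for ribosomal copies.

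Interferon and antigen presentation genes were higher in the 12-month than in the 3-month bleomycin library, where macrophage markers were higher too. RNA of macrophages in the suspension is argued against by the median ratio of the level in AT2-like cells to that in the macrophage-like cluster, 0.641 for the interferon list against at most 0.0236 for a macrophage marker. That cluster held 312 cells of the 12-month bleomycin library. With resolution 1 they were 206 macrophage-like cells, beside 107 in a T or NK-like cluster that the main setting did not separate. The reference cluster may thus hold T or NK cells too, which was not counted. Cells that captured macrophage transcripts are argued against by a list median of 2.75 in cells without a macrophage-marker count. These were 714 of 2499 cells in the 12-month and 1833 of 2420 in the 3-month bleomycin library. In thinned cells the list median was 2.73. This cannot decide on greater depth per cell, because random thinning keeps each gene's expected share of a cell's counts. An interferon response of the alveolar cells, the age of the mice and a difference between the pools of mice were not tested and stay open.

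Ribosomal copies were lower in both bleomycin libraries, with median log2 ratios of -2.04 at 3 and -1.73 at 12 months over 28 copies. Lower ribosomal transcript content is argued against, since the copies lay below the ribosomal protein genes by a difference of -1.66 at 3 and -1.41 at 12 months. Reads divided differently between near-identical genes in the libraries of the 2 days stay open as a candidate explanation, since 20 other pseudogenes were lower as well (-0.89 and -0.71). With 200 aligned bases, the higher level or both, the latter value was -0.58. Within a day the copies differed too. At 12 against 3 months their median was -0.44 between the PBS libraries (27 of 28 lower) and -0.27 between the bleomycin libraries (18 of 28). Other pseudogenes gave -0.41 and -0.15. A difference between the days would not account for these values. No biological explanation was tested.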
